A study of Rattus norvegicus with 12 samples.

How the data were processed

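White blood cells of male Sprague-Dawley rats, an outbred laboratory stock, were profiled for DNA methylation by reduced representation bisulfite sequencing. In this assay the enzyme MspI cuts at CCGG, short fragments rich in CpG are kept, and bisulfite turns unmethylated cytosines into uracil, so that a cytosine still read as C is counted as methylated. Per the labels' protocols, about 1000 ng of DNA was digested, fragments of 150 to 300 bp were selected, and the libraries were sequenced on one instrument type. The 12 libraries carry the same batch name in the labels and fall into 3 groups of 4 by their treatment labels: fluid percussion injury (FPI), a model of traumatic brain injury in which a fluid pulse strikes the exposed brain surface; sham surgery; and no procedure (control). The rats weighed 200 to 240 g and the blood was taken 1 week after surgery, after tests of learning. The labels name 12 samples but do not tie each one to an animal in words, so the p-values measure the spread between these samples.

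The deposited tables list single cytosines with the context (CG, CHG or CHH, where H is any base but G), the methylation level as a fraction, and the counts of methylated reads and of all reads. Reads were aligned with Bowtie to the rat build rn5, per the submitters' processing notes, and no version is given in the sources used here. The methylation caller and its filters are not given in the sources used here. The smallest deposited read count of a cytosine was 10 in every library, so the authors' tables hold no cytosine of lower coverage. The deposited fraction equalled methylated reads over all reads in every library, to within rounding of the last digit. All coordinates are 1-based positions in rn5 as deposited.

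From these tables the read counts of both strands of a CpG were summed. The 12 libraries listed between 6747409 and 9645538 cytosines and between 828218 and 1134514 CpGs. The median coverage of the 556533 CpGs listed in all 12 libraries ran from 19 reads (control 1) to 48 reads (FPI 4). By the number of cytosines listed, the libraries split into 2 sets of 6: control 1 to 4 with sham 1 and 2 (set A), and sham 3 and 4 with FPI 1 to 4 (set B). The split leaves no FPI library in the set of the control libraries. The mitochondrial genome was left out of all CpG tests, which left 556521 CpGs.

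Single CpGs were tested when their mean level over the 12 libraries lay between 5% and 95%, which left 198900. Tiles were non-overlapping windows of 1000 bp with at least 3 measured CpGs, their counts summed, and the same limits on the mean level, which left 37498. The test was a quasi-binomial logistic model of methylated and unmethylated read counts, with the group as a factor and all 12 libraries in the fit. Pearson dispersions were shrunk across features with squeezeVar of limma 3.58.1 in R 4.3.3. Groups were compared by a two-sided F test on the deviance with Benjamini-Hochberg adjustment over all features tested, and a feature was called at an adjusted p under 0.05. Every adjusted p of a CpG or tile comes from this test unless another tool is named. Differences are group means of library levels in percentage points, and SE is their standard error from the SDs of the 2 groups.

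The design set before the data were examined shrank dispersions to 1 prior for all features, and the test was first run in that form. On beta-binomial counts simulated for FPI vs sham, drawn for the 198900 real CpGs at their real coverages, that version gave 103 false calls among 180. With a prior that follows the mean coverage of a feature there were 9 false calls among 84, and 93.9% of changes of 40 points, 17.9% of changes of 20 points and 1.49% of changes of 10 points were recovered. For simulated tiles there were 17 false calls among 165, against 19 among 150 without the trend, and 100% of changes of 40 points, 92.5% of 20 points and 29.9% of 10 points were recovered. The coverage trend was adopted for both levels because of the simulated CpGs, after calls without it had been seen in the real data. The calls without it are given among the alternatives. Simulated samples shared 1 mean level per feature outside the added changes, with beta-binomial spread, and held no steps of whole alleles between samples. The shares of false calls and of recovered changes therefore need not hold in the real data.

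The mean CpG level of a library was the mean over the 556521 CpGs, and groups were compared by a two-sided exact permutation test over the 70 splits of 8 libraries, whose smallest p is 0.0286. The same test was used for the level of cytosines outside CpG on the autosomes, given as methylated reads over all reads. Families of such tests were adjusted by the Benjamini-Hochberg method. The level of all cytosines of the mitochondrial genome was used as a measure of cytosines that stayed unconverted.

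A CpG was called step-like when every one of the 12 libraries lay within binomial sampling error (p of at least 0.01) of a level of 3%, 50% or 95%, with more than 1 of these levels present and a range of at least 30 points. These are the levels a rat with 0, 1 or 2 methylated alleles would give, and the groups were not used in choosing them. At such CpGs the share of counts off the 3 levels was measured in each library, and a mixture of each library with each other one was fitted by maximum likelihood. This part, the subtraction of the mitochondrial level, the removal of step-like CpGs and the fit without control 1, control 3 and sham 3 were added after the data had been seen. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

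The rule for named features was fixed with the design. For each comparison it takes the called tiles with the 10 largest increases and 10 largest decreases, and the called CpGs with the 3 largest in each direction. Where fewer than 3 tiles passed, it takes the 5 of smallest p. Alternatives were a coverage minimum of 20, no filter on the level, removal of the CpGs of highest coverage, limma on logit levels with a pseudocount of 2, edgeR 4.0.16 with its quasi-likelihood test, a dispersion floor, other sets of libraries, a replicate block, a library offset, the library set as a term, libraries of the same set only, tiles of 500 bp or of at least 5 CpGs, a difference of at least 10 points and leaving out each library in turn. The replicate numbers did not pair the samples: deviations of same-numbered libraries from their group means had correlations between -0.0191 and 0.0181 over 12 pairs. No pair of libraries of a group agreed within sampling noise, as chi-square per CpG ran from 1.11 (control 1 and control 3) to 1.72. At CpGs step-like in the other libraries, deviations of control 1 and control 3 from the mean of those libraries had a correlation of 0.688 across CpGs. The control values at n = 4 may thus rest on fewer independent samples. The chi-square of 1.11 for control 1 and control 3 lay above binomial noise. Since PCR reads are not independent molecules, this does not show that they are separate samples. They were kept as 2 libraries, and each comparison was also made without them and sham 3.

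An annotation or genome of rn5 was not used here. Promoters, gene lists and classes of gene parts, which the design planned, were therefore not analysed here, and regions are named by position only. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the tables, and matplotlib 3.10.9 drew the figures.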

Results

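DNA methylation was measured in white blood cells of male rats in 12 samples, 4 after fluid percussion injury (FPI), 4 after sham surgery and 4 without a procedure (control), taken 1 week after surgery. The design asks which CpGs and regions of blood DNA differ after the injury beyond the surgery (FPI vs sham), after the surgery alone (sham vs control), and after both together (FPI vs control). The summed reads over all listed cytosines ran from 120116355 in control 1 to 329809647 in FPI 4. The CpGs measured in all libraries were covered by a median of 19 to 29 reads in the control group, 25 to 44 in the sham group and 37 to 48 in the FPI group.

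Most CpGs stood at either low or high levels. Of the 556521 CpGs measured in all libraries, 33.2% had a mean level under 5% and 31.0% a mean level of 95% or more. CpGs in tiles with 20 or more measured CpGs had a mean level of 5.98% ± 0.258 (SD, n = 4) in the control group. CpGs in tiles with 1 to 4 measured CpGs were at 82.1% ± 0.189 (SD, n = 4) there. Sites on the X chromosome had a mean level of 55.0% ± 0.201 (SD, n = 4) in the control group, and autosomal ones were at 54.0% ± 0.182.

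Cytosines outside CpG were read as methylated in 1.70% to 2.53% of reads in the 4 control libraries and sham 1 and 2, and in 0.383% to 0.402% in sham 3 and 4. The FPI libraries 2 to 4 lay between 0.403% and 0.479%, and FPI 1 was at 1.44%. The mitochondrial genome gave nearly the same values in each library, 1.55% to 2.605% in the control libraries and sham 1 and 2, and 0.306% to 0.421% in sham 3 and 4 and FPI 2 to 4. FPI 1 was at 1.82% there. The control libraries with sham 1 and 2 (set A) and the other 6 (set B) also differ in the number of cytosines listed, and this split bears on every level near 0.

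**Figure D1:**
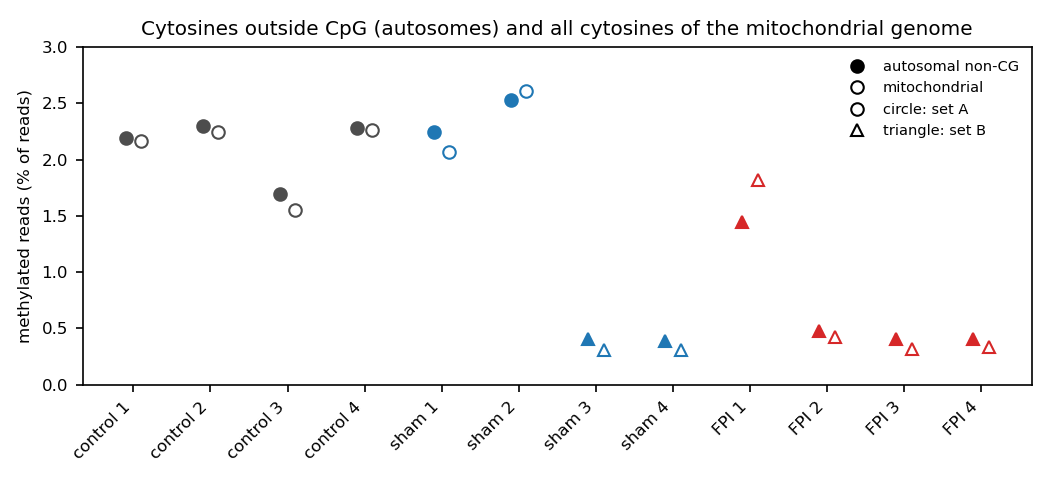
Methylated reads as a percentage of all reads (y axis) in each of the 12 libraries (x axis), for autosomal cytosines outside CpG (filled) and all mitochondrial cytosines (open). The 4 control libraries and sham 1 and 2 (circles) lie above the FPI 2 to 4 and sham 3 and 4 libraries (triangles) in both, and FPI 1 (triangle) is at 1.44% and 1.82%.

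Between FPI and sham, 13 of 37498 tiles differed, 5 higher and 8 lower in FPI. All 5 higher tiles were higher in FPI at each of their CpGs, and 4 of the 5 held 7 to 11 of them. The largest of these differences was on chromosome 3 (116808001 to 116809000), where the level was 85.9% ± 0.648 (SD, n = 4) in FPI and 56.7% ± 12.8 in sham, a difference of 29.2 points (SE 6.43, adjusted p = 0.0305 by the quasi-binomial test). The control group stood at 79.98% ± 7.01 there. On chromosome 13 (79190001 to 79191000) the 9 CpGs averaged 78.9% ± 2.76 (SD, n = 4) in FPI, 70.9% ± 3.46 in control and 60.1% ± 5.18 in sham. The difference from sham was 18.8 points (SE 2.93, adjusted p = 0.0132).

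On chromosome 2 (268931001 to 268932000) the level was 67.5% ± 4.42 (SD, n = 4) in FPI and 50.4% ± 5.78 in sham, a difference of 17.0 points (adjusted p = 0.0369), with 55.4% ± 3.29 in control. On chromosome 16 (82129001 to 82130000) 11 CpGs were at 51.3% ± 1.87 (SD, n = 4) in FPI, 38.1% ± 4.76 in sham and 40.4% ± 5.47 in control, and FPI exceeded sham by 13.2 points (adjusted p = 0.0487). In these 4 tiles every FPI library lay above every sham library, and each library had 165 to 610 reads per tile. None of the 4 was called for FPI vs control or for sham vs control. On chromosomes 3 and 13 the sham mean lay further from control than the FPI mean did. On chromosomes 2 and 16 the FPI mean lay further from it. Of the 4, those on chromosomes 3 and 13 stayed past the threshold when their step-like CpGs were removed, and the one on chromosome 16 moved to an adjusted p of 0.0503. The tile on chromosome 2 held 0 step-like CpGs, so that the removal left its difference as it was.

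**Figure D2:**
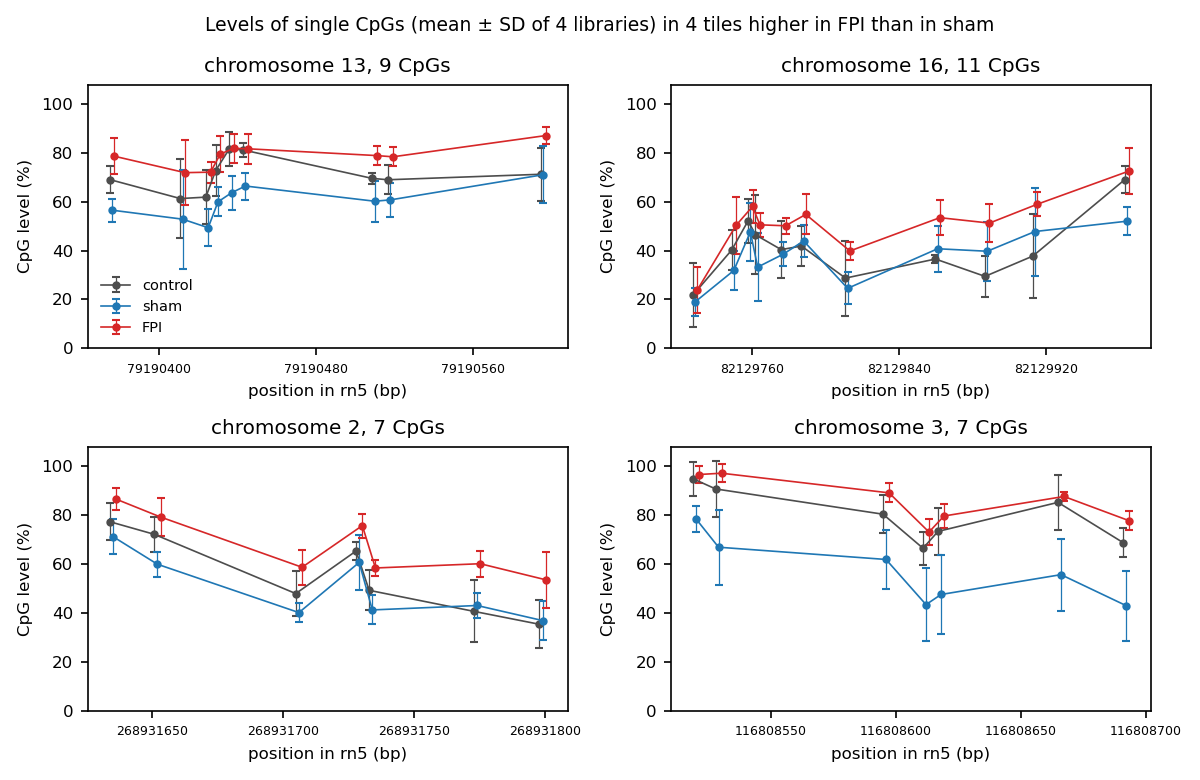
Level of each measured CpG (y axis, percent, mean ± SD of 4 libraries) along the position in rn5 (x axis, bp) in the 4 tiles of 7 to 11 CpGs that were higher in FPI than in sham. On chromosome 3 the control means lie between sham and FPI, and on chromosomes 2 and 16 the control and sham means lie below FPI at each CpG.

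The other 9 called tiles held 3 or 4 measured CpGs each, and in each the largest change was at a single step-like CpG. The remaining higher tile, on chromosome 7 (62737001 to 62738000), was at 97.98% ± 1.55 (SD, n = 4) in FPI and 82.2% ± 9.85 in sham, and its CpG at 62737268 differed by 39.9 points against 5.39 for the next. The tile with the smallest p lay on chromosome 14 (86572001 to 86573000), with 79.2% ± 0.913 (SD, n = 4) in FPI, 96.2% ± 1.29 in sham and 94.2% ± 1.99 in control (adjusted p = 5.0e-06). That difference came from the CpG at 86572055, which fell by 50.9 points while the next CpG fell by 0.410. A second tile on that chromosome (85558001 to 85559000) fell by 16.4 points, with its CpG at 85558020 lower by 49.7 points and the next unchanged in the mean.

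The largest decrease of a tile was on chromosome 13 (55675001 to 55676000), from 75.7% ± 7.37 (SD, n = 4) in sham to 42.3% ± 5.47 in FPI. All 3 of its CpGs were lower, the CpG at 55675722 by 71.1 points and the next by 20.1. The tile on chromosome 10 (107976001 to 107977000) fell by 26.7 points and those on chromosomes 19 (38560001 to 38561000) and 1 (250360001 to 250361000) fell by 17.9 and 17.6 points. The tiles on chromosomes 2 (132508001 to 132509000) and 6 (71497001 to 71498000) fell by 16.9 and 16.4 points. Of the 13 tiles, limma called 4 (0 higher and 4 lower in FPI, with 1894 tiles at an unadjusted p under 0.05) and edgeR 7 (2 higher and 5 lower). Within set B the quasi-binomial test called 4 tiles, 0 higher and 4 lower, of which 2 were among the 13, with 1975 at an unadjusted p under 0.05. With only the 2 groups in the fit it called 3, 0 higher and 3 lower. With at least 5 CpGs per tile it called 1, on chromosome 13 (79190001), and not those on chromosomes 3, 2 and 16. After removal of the step-like CpGs 3 tiles were called, all higher in FPI. The lower tiles of the 13 and the one on chromosome 7 were no longer tested there. They fell under the minimum of 3 CpGs or outside the limits on the mean level, so that none of them could be called again. The count depended on single libraries: it was 6, 7, 20 and 1 without FPI 1, 2, 3 or 4 and 5, 6, 6 and 1 without sham 1, 2, 3 or 4. The single tile left without FPI 4 or without sham 4 was lower in FPI.

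**Figure D3:**
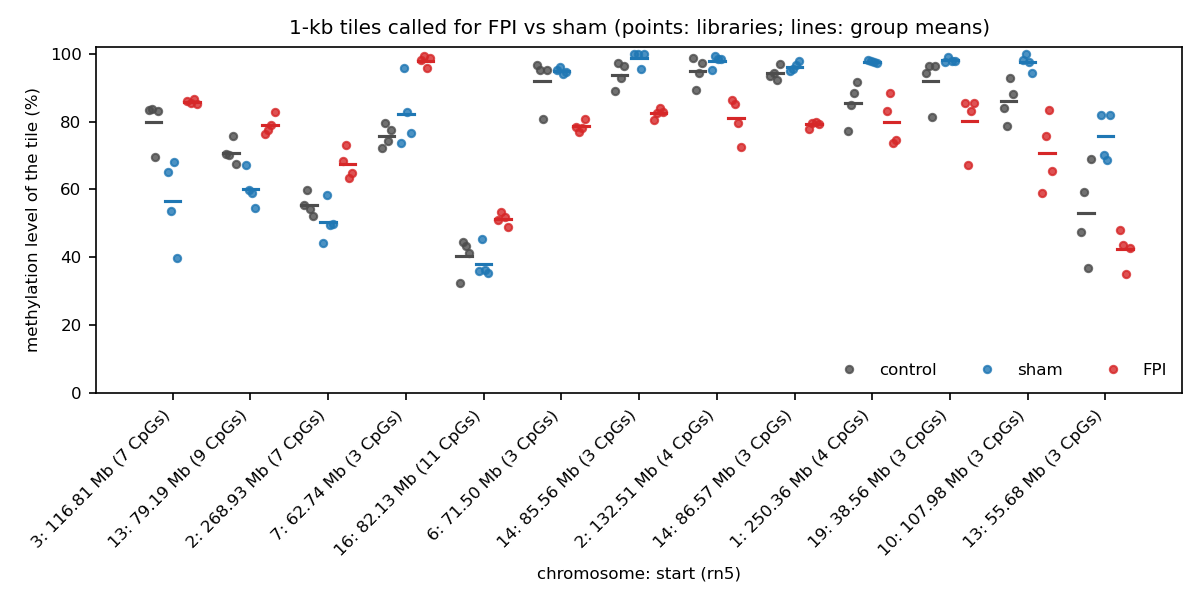
Methylation level (y axis, percent) of the 13 tiles called for FPI vs sham (x axis, chromosome and start in rn5), each point a library and each line a group mean. The 5 tiles on the left are higher in FPI than in sham, the 8 on the right lower, and most of the latter lie near 80% in FPI and above 94% in sham.

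At single CpGs, 81 of 198900 differed between FPI and sham, 42 higher and 39 lower in FPI, by 18.8 to 73.8 points with a median of 39.97. They lay on 17 chromosomes, with 16 on chromosome 2 and 11 on chromosome 3. The largest increases were at chromosome 3:64948358 (76.5% ± 26.6 in FPI and 9.89% ± 16.9 in sham, SD, n = 4), chromosome 8:94208490 (96.5% ± 1.18 and 36.2% ± 44.8) and chromosome 1:281824520 (65.8% ± 34.6 and 5.86% ± 9.56). The largest decreases were at chromosome 1:250360780 (25.4% ± 27.3 in FPI and 99.2% ± 1.67 in sham, SD, n = 4), chromosome 1:250383734 (26.3% ± 30.5 and 99.1% ± 1.79) and chromosome 10:107976930 (29.2% ± 34.4 and 100% ± 0). Their adjusted p ran from 0.00222 to 0.0326, at 10 to 56 reads per library. Of the 81 calls, 53 (65.4%) were step-like, that is, every library lay near the level of 0, 1 or 2 methylated alleles, against 5.196% of the tested CpGs. CpGs matched to the calls on spread held 47.6 step-like ones among 81 (permutation p = 0.12). With limma 17 CpGs and with edgeR 15 were called, and 127, 123, 145 and 125 were called without FPI 1, 2, 3 or 4.

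The mean CpG level was 53.6% ± 0.245 (SD, n = 4) in FPI and 53.8% ± 0.352 in sham, a difference of -0.199 points within the spread of the libraries (exact permutation p = 0.371). Within set B, FPI exceeded sham 3 and 4 by 0.101 points, where the 15 splits cannot reach the threshold. The non-CG level was 0.682% ± 0.508 in FPI and 1.39% ± 1.16 in sham (n = 4, exact permutation p = 0.429). Within set B the difference was 0.289 points (exact permutation p = 0.4), and 0.0355 points without FPI 1 (exact permutation p = 0.4). CHG and CHH cytosines gave differences of -0.672 and -0.721 points (exact permutation p = 0.371 and 0.429, n = 4).

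Between sham and control 1 of 37498 tiles passed, on chromosome 15 (3645001 to 3646000), where sham was at 73.3% ± 0.989 (SD, n = 4), control at 91.0% ± 5.21 and FPI at 73.4% ± 0.957 (adjusted p = 0.0377). It rested on the CpG at 3645055, which was at 0.784% ± 1.01 in sham, 0.905% ± 1.24 in FPI and 76.2% ± 21.9 in control (n = 4, adjusted p = 3.0e-06). The next 4 tiles by p did not pass. They were on chromosome 14 (5183001 to 5184000, 91.0% in sham and 75.2% in control, adjusted p = 0.317; 86418001 to 86419000, 77.6% and 66.6%, adjusted p = 0.546), chromosome 1 (137055001 to 137056000, 89.9% and 74.4%, adjusted p = 0.317) and chromosome 15 (8891001 to 8892000, 88.4% and 96.9%, adjusted p = 0.546). On chromosome 14 the former had all 5 CpGs and the latter all 10 in the same direction.

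Of 198900 CpGs 11 differed between sham and control, 6 higher and 5 lower in sham, and 9 of them were step-like. The largest increases were at chromosome 1:195684015 (59.0% ± 22.2 in sham and 0% ± 0 in control, SD, n = 4), chromosome 3:89342748 (60.3% ± 23.0 and 1.98% ± 2.31) and chromosome 1:31262350 (96.7% ± 3.84 and 51.6% ± 29.8). Besides the CpG on chromosome 15, the largest decreases were at chromosome 8:118654477 (1.04% ± 2.08 in sham and 48.8% ± 2.42 in control, SD, n = 4) and chromosome 10:63857585 (0.481% ± 0.962 and 40.5% ± 11.9). Their adjusted p ran from 3.0e-06 to 0.0313. The tile was lost without control 1, control 3 or any 1 of the 4 sham libraries and with limma and edgeR, each of which called 0 tiles (2575 and 2123 had an unadjusted p under 0.05). The CpG count was 152 without step-like CpGs (128 higher and 24 lower in sham) and 259 with only the 2 groups in the fit (195 higher and 64 lower). Within set A it was 273 (118 higher and 155 lower), and with the library set as a term 19 (5 higher and 14 lower). It was 5 without control 1 or control 2, 97 without control 3 (83 higher and 14 lower), 83 without control 1, control 3 and sham 3 (68 higher and 15 lower, 6 of them among the 11), 17 without control 4, 20 without sham 1 and 7 without sham 4.

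The mean CpG level was 54.0% ± 0.182 (SD, n = 4) in control, and sham minus control was -0.214 points (exact permutation p = 0.314). The non-CG level was 2.12% ± 0.285 in control and 1.39% ± 1.16 in sham (n = 4, exact permutation p = 0.371). Within set A, sham 1 and 2 lay above control by 0.0848 points in the mean CpG level and by 0.268 points in the non-CG level. CHG and CHH cytosines gave differences of -0.691 and -0.742 points (exact permutation p = 0.371 for both, n = 4).

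Between FPI and control 4 of 37498 tiles differed, 2 higher and 2 lower in FPI. On chromosome 15 (45001 to 46000) all 9 CpGs were higher, with 73.5% ± 4.91 (SD, n = 4) in FPI, 66.9% ± 9.63 in sham and 44.9% ± 11.3 in control (adjusted p = 0.0482). The tile on chromosome 7 named above was at 97.98% ± 1.55 in FPI and 75.9% ± 3.22 in control (n = 4, adjusted p = 0.0482). The lower ones were the tiles on chromosome 15 (3645001 to 3646000, 73.4% ± 0.957 and 91.0% ± 5.21, adjusted p = 0.0131) and chromosome 14 (86572001 to 86573000, 79.2% ± 0.913 and 94.2% ± 1.99, adjusted p = 1.2e-04). The chromosome 7 tile and both lower tiles rested on a single step-like CpG each, and the chromosome 14 and chromosome 7 tiles were also called against sham.

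Of 198900 CpGs 43 differed between FPI and control, 24 higher and 19 lower in FPI, and 32 of them were step-like. The largest increases were at chromosome 3:160215321 (85.1% ± 5.42 in FPI and 23.2% ± 18.7 in control, SD, n = 4), chromosome 7:62737268 (96.8% ± 1.55 and 35.1% ± 10.6) and chromosome 16:8540831 (60.8% ± 25.3 and 0.735% ± 1.47). The largest decreases were at chromosome 15:8891647 (0.962% ± 1.92 in FPI and 88.6% ± 22.7 in control, SD, n = 4), chromosome 15:3645055 (0.905% ± 1.24 and 76.2% ± 21.9) and chromosome 10:66715186 (0.758% ± 1.52 and 75.9% ± 28.6). With limma 1 tile and 13 CpGs and with edgeR 1 tile and 7 CpGs were called, and a dispersion prior without the coverage trend gave 2 tiles. With the library set as a term the quasi-binomial test called 0 tiles, and 1777 had an unadjusted p under 0.05. It then called 23 CpGs, of which 4 were among the 43. Over all alternatives, the set term included, the tile differences ran from 25.1 to 34.6 points on chromosome 15 (45001) and 19.5 to 27.0 on chromosome 7. Those of the lower tiles ran from -19.1 to -15.1 on chromosome 15 (3645001) and -17.0 to -14.1 on chromosome 14. The tile count was 1 without control 1 and 2 without control 2, control 4 or FPI 4, and the CpG count was 123 without FPI 3 (72 higher and 51 lower in FPI). Without control 1, control 3 and sham 3, which may be mixtures of libraries, the CpG count was 120 (85 higher and 35 lower), of which 24 were among the 43.

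The mean CpG level was lower in FPI than in control, with a difference of -0.413 points and all 4 FPI libraries below all 4 control libraries (53.6% ± 0.245 and 54.0% ± 0.182, SD, n = 4, exact permutation p = 0.0286, the smallest the design allows, and 0.12 after Benjamini-Hochberg adjustment over 21 tests of levels). After subtraction of the mitochondrial level of each library the direction turned, with FPI minus control at 0.214 points (exact permutation p = 0.257). Without FPI 3 or without control 2 the exact permutation p was 0.0857. CpGs of mean level under 5% were at 1.12% ± 0.473 in FPI and 2.45% ± 0.264 in control (n = 4, exact permutation p = 0.0286, 0.171 after Benjamini-Hochberg adjustment over 24 tests). After subtraction they were at 0.398% and 0.401% (exact permutation p = 1). Those in tiles with 1 to 4 CpGs had means of 82.1% in both groups. The non-CG level differed by -1.43 points (0.682% ± 0.508 and 2.12% ± 0.285, n = 4, exact permutation p = 0.0286, 0.12 after Benjamini-Hochberg adjustment over the same 21 tests), and CHG and CHH cytosines by -1.36 and -1.46 points. Without any 1 of the control libraries the exact permutation p of the non-CG level was 0.0571. All 4 FPI libraries are in set B and all 4 control libraries in set A, so that this comparison has no value within a set. Sham spans both sets, with non-CG levels of 2.24% and 2.53% in set A and 0.402% and 0.383% in set B.

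**Figure D4:**
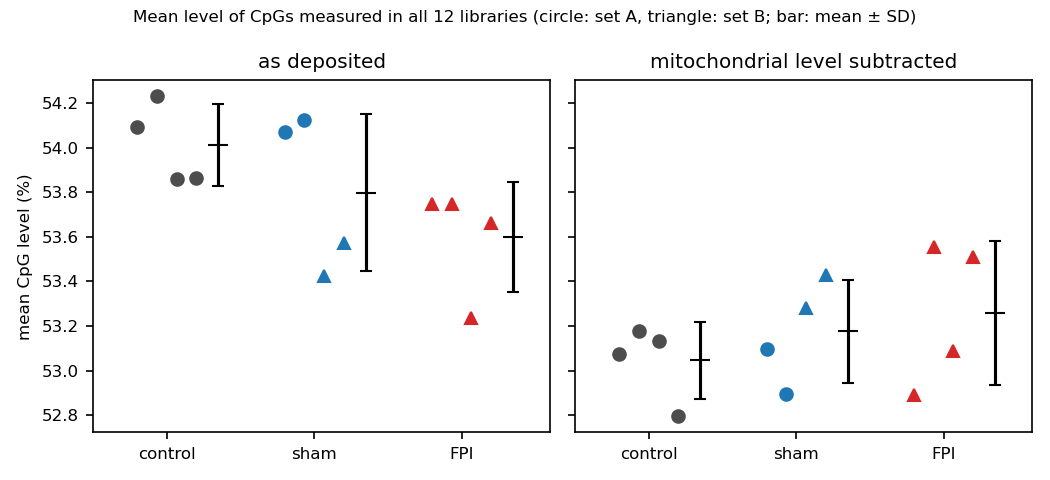
Mean level (y axis, percent) of the CpGs measured in all libraries for each library by group (x axis), as deposited and after subtraction of the mitochondrial level of each library, with the group mean ± SD. As deposited, the FPI libraries lie between 53.2% and 53.7%, below the control libraries, and after subtraction the groups overlap, with FPI minus control at 0.214 points.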

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

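The tests of explanations in this part were chosen after the results were seen, including the subtraction of the mitochondrial level and the removal of step-like CpGs. The fits of CpGs and tiles with limma, within the library set and with only the 2 groups, and of tiles with at least 5 CpGs or without single libraries, were planned before, but not those of the non-CG level.

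Among 135 groups of 4 libraries, 25 libraries stood apart from the other 3 of their group by the ratio of the gap to the range. Chance gives about 1 in 20 for values without ties, but in 11 of the 25 the other 3 libraries were equal, where any difference stands apart. The 4 values of FPI 1 outside CpG are measures of 1 property. Of these, 6 of 27 groups were library measures. FPI 3 had a mean CpG level of 53.2%, against 53.7% in each of the other FPI libraries. FPI 1 was at 1.45% for CHG, 1.44% for CHH, 1.44% for all non-CG cytosines and 1.82% for mitochondrial cytosines, and the other FPI libraries lay at no more than 0.520%, 0.463%, 0.479% and 0.421%. Control 3 had a mitochondrial level of 1.55%, below the 2.17% to 2.27% of the other control libraries.

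The other 19 were at named CpGs and tiles. Some lay far from their group: sham 4 at 35% at chromosome 3:64948358 (others 0% to 4.55%), FPI 2 at 0% at chromosome 8:118654477 (others 51.2% to 59.4%) and control 4 at 54.5% at chromosome 15:8891647 (others 100%). Others lay a few points from a group at 0%, 50% or 100%: sham 3 at 96.7% at chromosome 1:250360780, 96.4% at chromosome 1:250383734 and 1.92% at chromosome 10:63857585, FPI 4 at 2.33% at chromosome 3:89342748 and 3.85% at chromosome 15:8891647, control 4 at 45.2% and sham 1 at 4.17% at chromosome 8:118654477, control 3 at 2.94% at chromosome 16:8540831, and FPI 1 at 3.03% at chromosome 10:66715186. Among tiles, control 3 was at 69.5% on chromosome 3 (116808001; others 83.2% to 83.7%), 81.5% on chromosome 19 (38560001; others 94.2% to 96.5%) and 80.8% on chromosome 6 (71497001; others 95.2% to 96.7%). Sham 2 was at 45.2% on chromosome 16 (82129001; others 35.2% to 36.2%) and 99.1% on chromosome 19 (38560001), FPI 2 at 67.1% there, and sham 3 at 95.6% on chromosome 14 (85558001; others 100%).

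The single CpGs called for FPI vs sham stood alone. In 71 of 81 calls the median CpG within 200 bp moved by under 25% of the call, with a median of 0.410 points against 39.97, which argues against a change of the whole region. Of the 81 calls, 80 remained after subtraction of the mitochondrial level and 47 within library set B. The highest mitochondrial level, 2.605% in sham 2, lay below the smallest call of 18.8 points, so that the subtraction could hardly lose calls. These sizes argue against incomplete conversion as the whole cause. The fit within set B reuses libraries that gave the calls, so that the 47 cannot tell whether the set is a cause. Calls lay within 1 kb to 2 Mb of another call in 39 of 81 cases against 14.9 among CpGs matched on spread. By 10000 random draws of matched CpGs p was 0.0001, the smallest possible. Called CpGs of the same locus, such as those in the chromosome 3 tile (116808001), were counted separately. The draws took each CpG on its own, so that the excess may be inflated. Sequence variants or haplotypes carried unequally by these outbred samples are a candidate explanation. The share of step-like CpGs itself, 53 against 47.6 in matched CpGs, was within chance (permutation p = 0.12), while for FPI vs control it was 32 against 25.7 (permutation p = 0.027), and an effect of the injury on such CpGs stays open, as no genotypes were used here.

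Control 1, control 3 and sham 3 held more CpGs off the levels of 0, 1 or 2 alleles (8.12%, 13.2% and 12.2%) than the other 9 libraries (0.823% to 3.28%). Lower 95% bounds of at least 8.67% in control 3 and sham 3 lay above the highest upper bound of the other 9 at 6.36%. The lower bound of control 1 was 5.16% and did not. Alleles of relatives stay at those levels, so that relatives alone would not give such counts. The 3 libraries were picked by this same share, however, so that the bounds are no separate test. Relatives in addition to another source stay open. A mixture with the best partner library raised the log likelihood by at least 200.4 in the 3 libraries and by at most 0.753 in the other 9. Every other partner also raised it in the 3 libraries, the next best by 95.93 in control 1, 157.26 in control 3 and 91.76 in sham 3. A gain alone thus partly restates the counts off the levels and does not show mixing. Fitted shares of the best partners were 47% of control 3 in control 1, 41% of control 1 in control 3 and 11% of sham 2 in sham 3. These partners gained more than the next ones, so that mixed DNA or reads may be the source. If so, control 1 and control 3 are not independent samples, and the control SDs and p-values at n = 4 rest on fewer. Relatives were the only biological explanation considered.

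The non-CG level differed by -1.43 points between FPI and control. The mitochondrial level followed the non-CG level to within 0.378 points in all 12 libraries, so that incomplete conversion may account for it. The uninjured sham 3 and 4, of set B, lay at least 1.29 points below every control library, against a range of 0.603 among those, which argues against the injury as the whole cause. Within the sham group set B lay at least 1.84 points below set A, so that the level may follow the library set, apart from FPI 1 at 1.44% in set B. Within set B, FPI minus sham was 0.289 points and 0.0355 without FPI 1, and the 15 splits are too few to test an added effect of the injury.

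Of the 4 tiles of 7 to 11 CpGs that were higher in FPI than in sham, 3 of 4 passed without step-like CpGs. Of these 3, the one on chromosome 2 held 0 step-like CpGs, so that its result tests nothing about them. Limma, the fit within set B and the fit of only the 2 groups called 0 higher tiles (4, 4 and 3 lower, with 1894, 1975 and 2106 tiles at an unadjusted p under 0.05). With at least 5 CpGs per tile 1 of the 4 was called, and without FPI 4 or without sham 4 the quasi-binomial test called 0 higher tiles and 1 lower (2245 and 2149 at an unadjusted p under 0.05). The differences themselves ran over all alternatives from 23.6 to 32.9 points on chromosome 3, 16.9 to 22.1 on chromosome 13, 15.0 to 19.6 on chromosome 2 and 12.2 to 15.6 on chromosome 16.

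Other splits of 8 libraries, 35 for each comparison with the real one, were tested as well. For tiles, 1 of the 35 splits had as many calls for FPI vs sham (13, highest other 7) and 1 for FPI vs control (4, highest other 2), the real split in both. A share of 1 in 35 is the smallest these splits can give, and it was not adjusted over the 6 counts. The splits treat the 8 libraries as exchangeable, whereas in FPI vs sham the set A libraries are both sham. For FPI vs control the real split is also set B against set A, and control 1 and control 3 may not be independent. The real splits gave the most tiles, but chance is not excluded by this. For sham vs control 3 of 35 splits had as many as 1 tile. For CpGs, 2 splits gave as many as the 81 calls of FPI vs sham (highest other 96), 7 as many as 11 for sham vs control (highest other 30) and 6 as many as 43 for FPI vs control (highest other 123). The other splits had medians of 42, 4.5 and 10.5 called CpGs, in the same order. Chance is not excluded for these counts.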

How the results depend on the processing

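The subtraction of the mitochondrial level, the removal of step-like CpGs, the fit without control 1, control 3 and sham 3, the dispersion prior without the coverage trend and all alternatives of the non-CG level were chosen after the results were seen. A coverage minimum of 5 gives the same data, and promoters, gene lists and gene classes were not run. For the changes below the cause was not tested.

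Counts of called CpGs are given for FPI vs sham (81), sham vs control (11) and FPI vs control (43), in this order. They were 16, 3 and 11 at a coverage minimum of 20, where 62032 CpGs were tested against 198900. Called CpGs of lower coverage were not tested there. Without the filter on the level, with 556521 CpGs tested, the counts were 3, 1 and 2. The counts were 17, 5 and 13 with limma, and 15, 4 and 7 with edgeR. With the library set as a term they were 132, 19 and 23. Within the set 123 were called for FPI vs sham and 273 for sham vs control. With only the 2 groups in the fit sham vs control had 259 and FPI vs control 104, without the 3 libraries 83 and 120, and without step-like CpGs sham vs control had 152. Without the coverage trend they were 81, 11 and 37.

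For tiles of FPI vs sham (13) the count was 2 at a coverage minimum of 20, where 10875 tiles were tested against 37498. It was 3 without step-like CpGs, 6 at 500 bp, 1 with at least 5 CpGs, 4 with limma and 7 with edgeR. It was 3 with only the 2 groups, 5 with the set as a term, 4 within the set and 9 without the coverage trend. Without step-like CpGs or with at least 5 CpGs, the called tiles of 3 or 4 CpGs were not tested. For sham vs control (1) the count was 0 with the mitochondrial level subtracted, without step-like CpGs, with at least 5 CpGs, with limma, with edgeR, without the coverage trend, with only the 2 groups, within the set and without the 3 libraries, where 1143 to 2575 tiles had an unadjusted p under 0.05. The tile called in the main test held 4 CpGs, 1 of them step-like. It was not tested without step-like CpGs or with at least 5 CpGs, so that its loss there was fixed in advance. For FPI vs control (4) the count was 2 at a coverage minimum of 20, with the mitochondrial level subtracted, at 500 bp, without the coverage trend and with only the 2 groups, 1 with limma and 1 with edgeR. It was 0 in the quasi-binomial test without step-like CpGs (2239 at an unadjusted p under 0.05), with at least 5 CpGs (1397) and with the set as a term (1777). The chromosome 15 tile (45001) held 0 step-like CpGs and kept its 28.6 points without them, with an adjusted p of 0.0626 in that test. The other called tiles of FPI vs control were not tested without step-like CpGs or with at least 5 CpGs.

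The replicate numbers do not pair the samples. With a replicate block the CpG counts were 242, 77 and 159, the tile of sham vs control was not called (0, with 2130 at an unadjusted p under 0.05), and the FPI vs control differences of -0.413 points (mean CpG level) and -1.43 points (non-CG level) had an exact p of 0.125, the smallest possible.

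The mean CpG level of FPI vs sham reversed to 0.179 points over all CpGs of each library, 0.0834 after subtraction and 0.101 within the set. For sham vs control it reversed to 0.130 after subtraction and 0.0848 within the set. For FPI vs control it was 0.214 after subtraction, -0.0305 over all CpGs of each library, -0.762 as reads over reads and -0.449 without the 3 libraries. The non-CG level reversed within the set to 0.289 (FPI vs sham; 0.0355 without FPI 1) and 0.268 (sham vs control), and for FPI vs control it was -1.61 without the 3 libraries (exact p = 0.0667, the smallest possible).

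Leaving out 1 library gave 68 to 145, 5 to 97 and 33 to 123 called CpGs, and 1 to 20, 0 to 1 and 1 to 5 called tiles. The mean CpG level ranged from -0.323 to -0.0776, -0.324 to -0.0897 and -0.464 to -0.292 points, and the non-CG level from -1.04 to -0.327, -1.11 to -0.393 and -1.69 to -1.34. Named CpGs kept their direction in 397 of 397 alternatives and their side of the threshold in 306, and the 18 called tiles kept their direction in 409 of 409 and their call in 214. Features that an alternative no longer tested are not counted here, nor are tiles of 500 bp. At a coverage minimum of 20, for example, 3 named CpGs kept their call, 1 lost it and the rest were not tested. In many of the counted alternatives, such as another test on the same counts, the difference was the main one by construction and its direction could not turn. The alternative of at least 10 points could not lose a call, as every named call exceeded it. At the real coverages 17.9% of simulated changes of 20 points at single CpGs were recovered, and depth itself was not varied.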

Other observations

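These values and their test were chosen after the data were seen. In the 5 libraries of low non-CG level (sham 3 and 4, FPI 2 to 4), over cytosines listed in all 12 libraries, CHH cytosines followed by A were at 0.547%, those followed by T at 0.367% and those followed by C at 0.321%. In CHG context the levels were 0.533%, 0.341% and 0.460%. Of the CHH cytosines before A, 1852 of 787220 stood at 10% or more and held 21.1% of the methylated reads, and of the CHG cytosines before A, 754 of 477123 held 20.8%. Of the CHG cytosines before C, 180 of 110269 did so and held 27.5%. Without such cytosines the levels were 0.432%, 0.423% and 0.334%.

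For FPI vs control, 14 of the 43 called CpGs lay within 1 kb to 2 Mb of another call, against 4.64 among CpGs matched on spread (permutation p = 0.0036), and for sham vs control 0 of 11 did against 0.286.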
